A study of Mus musculus with 3 samples.

How the data were processed

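Mouse small intestine was collected from wild-type, untreated animals 15.5 and 17.5 days into embryonic development (E15.5, E17.5) and 7 days after birth (P7), and each stage gave 1 droplet library of the Chromium 3′ v2 kind, which reads the 3′ end of transcripts and tags each captured molecule with a unique molecular identifier (UMI). Per the labels' protocols, epithelial and mesenchymal fractions were combined, stained, and sorted as viable cells that were either positive for Epcam, a surface protein of epithelial cells, or negative for Epcam, for the endothelial protein CD31 and for the blood cell protein CD45. The sort therefore set the share of epithelial cells in each library and removed most endothelial and blood cells. The strain, the sex and the number of animals per library were not given in the sources used here.

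The deposited values are raw UMI counts per gene and cell, whole numbers with no normalization, per the file headers and the values. Cell Ranger 7.2.0 and the genome builds mm10 and GRCm38 are named in the submitters' processing notes, which give no parameters. The counts had been filtered before deposit: every cell held 501 to 6989 detected genes and under 15% mitochondrial UMIs, and no filter of this kind is stated. All 3 libraries share 1 list of 22100 gene symbols, in which later libraries use entries that earlier ones leave empty, and 1866, 1331 and 1952 symbols had no count in the E15.5, E17.5 and P7 library. A gene with no count in a whole library can therefore be a gene that was taken out before deposit. The barcode names given for the 3 libraries are identical, 8447 names that match the number of cells at E15.5 alone, so barcodes were not used and no cell is named here.

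Depth per library was 93501273 UMIs over 8447 cells at E15.5, 94023160 UMIs over 11598 cells at E17.5 and 116038115 UMIs over 8391 cells at P7. The cell filter set here (500 or more genes and under 15% mitochondrial UMIs) removed 0 cells, since the deposited counts already met it. Scrublet, a doublet caller that scores cells against simulated doublets, was run per library from scanpy 1.11.5 with an expected rate of 6%. Its own threshold marked 243 cells (2.88%) at E15.5, 453 cells (3.91%) at E17.5 and 389 cells (4.64%) at P7, which were removed and had median depths of 17076, 14247 and 21735 UMIs against 8382, 6111 and 13744.5 UMIs in the kept cells.

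Each library was clustered by itself, so that a cluster cannot be a stage: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used with 15 neighbours, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) was run at resolution 1 with seed 0. Clusters were named from marker lists of 11 classes (epithelial, fibroblast, smooth muscle, pericyte, interstitial cell of Cajal, mesothelial, glial, neuronal, endothelial, immune and erythroid). The name went to the class with the highest mean over its 5 best marker scores, a score being the log2 ratio between the cluster and the median of all clusters of the 3 libraries with a pseudocount of 20 CPM. Erythroid markers were not allowed to name a cluster, since haemoglobin RNA was spread over all classes. A cluster stayed unnamed with under 3 detected markers (a score of at least 1, in at least 25% of its cells), with a second class within 1 log2 unit, with none of its own markers among its 10 leading genes (in at least 50% of its cells), or with more markers of another class there. This scoring was chosen after the data had been seen, while the markers were fixed earlier. Cells were summed per class and library, and levels are given as CPM, the UMIs of a gene scaled to 1e6 UMIs of that class. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.

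There is 1 library per stage, so no test between stages exists, and no p-value, standard error or count of changed genes was made from cells. Levels carry exact Poisson intervals, shares exact Clopper-Pearson intervals, and ratios exact conditional binomial intervals, all at 95% and all covering counting error only: differences between animals, litters, dissections or sorts are not in them. A gene with under 3 UMIs in a library is set against a floor of 3 UMIs. The steps compared were E17.5 against E15.5 and P7 against E17.5, within epithelial-like, fibroblast-like and smooth-muscle-like cells.

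Of 22 gene lists, those for mesenchymal cells were STRIPAK complex, Hippo core, YAP/TAZ targets, Hedgehog response, WNT ligands and modulators, BMP ligands and antagonists, smooth muscle contractile, extracellular matrix, cell cycle, imprinted growth genes, PDGFRA-high subepithelial, CD81 CD34 adventitial, and dissociation and stress. Epithelial-like cells were described with STRIPAK complex, Hippo core, YAP/TAZ targets, cell cycle, imprinted growth genes and dissociation and stress, and with lipid absorption, brush border and digestion, suckling enterocyte, goblet, enteroendocrine, crypt stem, fetal epithelium, epithelial signals, and antimicrobial and mucosal defence. Each list is given as the median log2 ratio over members with 30 or more UMIs in either library, with an interval from 1000 Poisson redraws. For part of the lists the number of members at least 1.5-fold higher or lower is given. For part of them the percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, is given. The percentile describes these libraries and is no test.

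Genes were named by a rule: Slmap and Stk24 first, then, per class and step, the 5 genes with the highest and the 5 with the lowest log2 ratio among those with at least 100 CPM and 30 UMIs in the higher library. Mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes were left out, as was any gene over 5 times higher in another class of the higher library, a guard against RNA that leaks between droplets (free RNA). Up to 2 members at each end of each list serve as examples. The lists, the markers, this rule, the cell filter, the clustering settings and all but 2 of the alternatives were fixed before the data were examined. The 2 added later were the smooth-muscle-like clusters with both Actg2 and Des among their 10 leading genes, called visceral clusters, and the restriction of lists to members that pass the guard.

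Cells in cycle were counted as cells with 2 or more UMIs from the cell cycle list after every cell was thinned at random to 2000 UMIs, leaving out shallower cells. Other settings tried were no cell filter, a stricter one (1000 genes, 10% mitochondrial), no doublet removal, resolutions 0.5 and 2, the 3 libraries clustered together, scaling by the median ratio of genes with 100 or more UMIs in both libraries, totals without mitochondrial, ribosomal and the 50 most abundant genes, the mean of each cell's own CPM, and no UMI minimum with a pseudocount of 0.5 UMI. For cells in cycle they were 1000 UMIs, 4 or more cell cycle UMIs, and no thinning.

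The ratios and their intervals were run on simulated data, with class sums drawn from Poisson distributions at the real class means and totals. In each comparison 200 genes were changed by known folds. No variation between cells, animals or libraries was simulated, so the shares below describe counting error only. For fibroblast-like cells, E17.5 against E15.5, 12770 genes were run, and the interval lay on the right side of 0 for 90.9% of genes changed 1.5-fold and 98.5% of those changed 2-fold. In P7 against E17.5, with 12671 genes, those shares were 75.0% and 89.4%. Smooth-muscle-like cells gave 83.6% and 96.9% at the first step (11156 genes) and 69.1% and 83.1% at the second (10683 genes). Epithelial-like cells gave 91.2% and 100% at the first step (12484 genes) and 87.9% and 93.7% at the second (14239 genes). Intervals of unchanged genes held the true ratio for 95.1% to 95.8% of genes in the 6 comparisons. The intervals assume the same Poisson model as the draws, so this checks the calculation and not how well the model describes the data.

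Gene positions were taken from the GENCODE M21 annotation of GRCm38. Endothelial, immune and mesothelial markers named no cluster under these rules, and the unnamed clusters were left out of the comparisons. Immune was still the best class of the unnamed clusters 25 at E15.5 and 23 at E17.5, with 33 and 168 cells. Both had Tyrobp, Srgn and Cd52 among their leading genes, and epithelial markers scored within 1 log2 unit of the immune ones.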

Results

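Single-cell transcriptomes of the small intestine of wild-type mice were measured at E15.5, E17.5 and P7, to describe the cells of the gut wall over the period in which the gut elongates. The series centres on 2 genes, Slmap and Stk24, the latter encoding the kinase MST3. Each stage is 1 library: 8447 cells and 93501273 UMIs at E15.5, 11598 cells and 94023160 UMIs at E17.5, and 8391 cells and 116038115 UMIs at P7, with medians of 8503, 6262.5 and 14014 UMIs per cell. Mitochondrial genes held 3.80%, 4.80% and 7.80% of the UMIs and haemoglobin genes 0.581%, 1.34% and 0.0373%, in the same order. There were no replicates, so stages are set side by side, and every interval is at 95% and covers counting error only. Log2 ratios are later over earlier, pairs of CPM values are given with the earlier stage first, and where such a pair has no interval beside it, the interval of its log2 ratio excluded 0. Brackets after a list's median hold its interval.

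Epithelial-like, fibroblast-like, smooth-muscle-like and neuronal-like cells were found in all 3 libraries. Epithelial-like cells were 15.8% (15.0 to 16.6%) of kept cells at E15.5, 14.0% (13.4 to 14.7%) at E17.5 and 75.6% (74.6 to 76.5%) at P7, shares that the sort for Epcam set. Of the 6910, 9585 and 1955 non-epithelial cells, fibroblast-like cells made up 48.5% (47.3 to 49.7%), 47.3% (46.3 to 48.4%) and 53.2% (51.0 to 55.4%), and neuronal-like cells 9.51%, 9.36% and 9.003%. Smooth-muscle-like cells made up 22.0% (21.0 to 23.0%) at E15.5, in clusters 4, 6, 16 and 17, and 13.9% (13.2 to 14.6%) at E17.5, in clusters 3, 20, 25 and 27. At P7 they made up 28.0% (26.0 to 30.1%), in clusters 11, 19 and 25. The leading genes of the P7 clusters differed from the earlier ones. Clusters 11 and 25, with 428 and 33 cells, were led by Eln (elastin), Tagln, Acta2 and Myh11. Their second class was pericyte, at mean scores of 3.89 and 3.46 against 5.88 and 5.50 for smooth muscle. In the muscle clusters of E15.5 and E17.5 the second class was fibroblast. Which kind of muscle clusters 11 and 25 hold was not tested. Of the 3 clusters only cluster 19, with 87 cells, had Actg2 and Des, the enteric actin and desmin of gut muscle, among its leading genes. The muscle shares are therefore not compared between stages. Clusters of that visceral kind held 19.2%, 13.9% and 4.45% of non-epithelial cells.

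Glial-like cells, led by Fabp7, made up 8.18% of non-epithelial cells at E17.5 and 3.38% at P7, and cells resembling interstitial cells of Cajal, the Kit-positive pacemakers of gut muscle, made up 4.23% and 1.74%. The P7 classes held 66 and 34 cells, and no P7 cell had the glial name without doublet removal or the Cajal name under the stricter cell filter. No E15.5 cluster carried either name, but clusters 12 and 21 there had glial and neuronal markers at similar strength and cluster 9 had Kit and Etv1 among its leading genes. With the 3 libraries clustered together, 197 E15.5 cells carried the glial name and 471 the Cajal one. Pericyte-like cells made up 2.33% at E15.5 and 0.939% at E17.5 and named no cluster at P7, which is 161, 90 and 0 cells. Their counts were 72, 153 and 9 with the libraries clustered together, 0 at E15.5 at resolution 0.5 and 503 at E17.5 without doublet removal. The shares of these 3 classes are therefore not compared between stages. Unnamed clusters held 17.7%, 16.0% and 4.65% of non-epithelial cells. At E17.5 the fibroblast-like clusters 1, 2, 5 and 6 had the inflammatory chemokine genes Ccl2, Cxcl1 or Cxcl10 among their leading genes, beside collagens and Dcn.

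Slmap encodes a tail-anchored membrane protein that belongs to STRIPAK, a complex of the phosphatase PP2A with kinases, and Stk24 encodes MST3, a STE20-family kinase found in the same complex. Slmap (ENSMUSG00000021870.17) lies on the minus strand of chromosome 14 at 26413168 to 26534931 in GRCm38, and Stk24 (ENSMUSG00000063410.8) on the minus strand of chromosome 14 at 121286343 to 121380011. By point value Slmap was highest among the named classes in smooth-muscle-like cells at each stage, at 167 CPM (160 to 174) at E15.5, 292 CPM (282 to 303) at E17.5 and 184 CPM (168 to 202) at P7. In fibroblast-like cells it stood at 29.1 CPM (27.1 to 31.1), 33.4 CPM (31.1 to 35.7) and 53.9 CPM (47.7 to 60.7), and in epithelial-like cells at 38.4, 36.7 and 46.0 CPM. Cells resembling interstitial cells of Cajal had 97.7 CPM (83.3 to 114) at E17.5 and 153 CPM (97.3 to 230.3) at P7, where their 34 cells held Epcam at 614 CPM against 2262 CPM in epithelial-like cells. These Slmap levels were above those of the glial-like, neuronal-like and pericyte-like cells, which lay between 18.6 and 42.3 CPM.

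The step from E17.5 to P7 in muscle depended on the clusters in the class. Slmap had a log2 ratio of 0.81 (0.73 to 0.89) at E17.5 against E15.5 and -0.67 (-0.81 to -0.53) at P7 against E17.5 in all smooth-muscle-like cells. In visceral clusters alone the ratios were 0.71 (0.63 to 0.79) and 0.19 (-0.03 to 0.39), and the levels 178, 292 and 333 CPM (288 to 382 at P7, 199 UMIs in 87 cells). These 87 cells also held epithelial RNA, with Fabp2 at 849.6 CPM and Cym at 293 CPM, against 8292 and 911 CPM in the epithelial-like cells of P7. Fibroblast-like cells lay in clusters 1, 2, 3, 7, 11, 18 and 22 at E15.5, 1, 2, 5, 6, 7, 12 and 18 at E17.5 and 9, 12, 18, 20 and 28 at P7. Their Slmap ratios were 0.20 (0.06 to 0.34) and 0.69 (0.49 to 0.89), the latter 0.36 at clustering resolution 2. Slmap was over 5 times higher in muscle than in these cells at E15.5 and at E17.5, so the first ratio did not pass the guard against free RNA. At P7, the higher library of the second ratio, muscle held 184 CPM against 53.9 CPM, under 5 times. The second ratio therefore passed the guard, although visceral clusters held 333 CPM. Stk24 differed less between classes. It had 41.3, 47.0 and 39.5 CPM in fibroblast-like cells, 47.2, 45.2 and 48.9 CPM in epithelial-like cells and 26.2, 24.8 and 24.0 CPM in neuronal-like cells. In smooth-muscle-like cells Stk24 stood at 36.7 CPM (33.5 to 40.1), 29.1 CPM (26.0 to 32.5) and 44.3 CPM (36.4 to 53.3), while in visceral clusters it was 18.4 CPM (9.18 to 32.9) at P7, from 11 UMIs. Its log2 ratio in muscle was -0.33 (-0.54 to -0.13) at the first step and 0.60 (0.28 to 0.92) at the second, against -0.66 (-1.68 to 0.20) in visceral clusters. Epithelial-like cells gave -0.07 (-0.20 to 0.06) for Slmap and -0.06 (-0.18 to 0.05) for Stk24 at the first step, and scaling by the median ratio of genes turned both to 0.07.

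**Figure D1:**
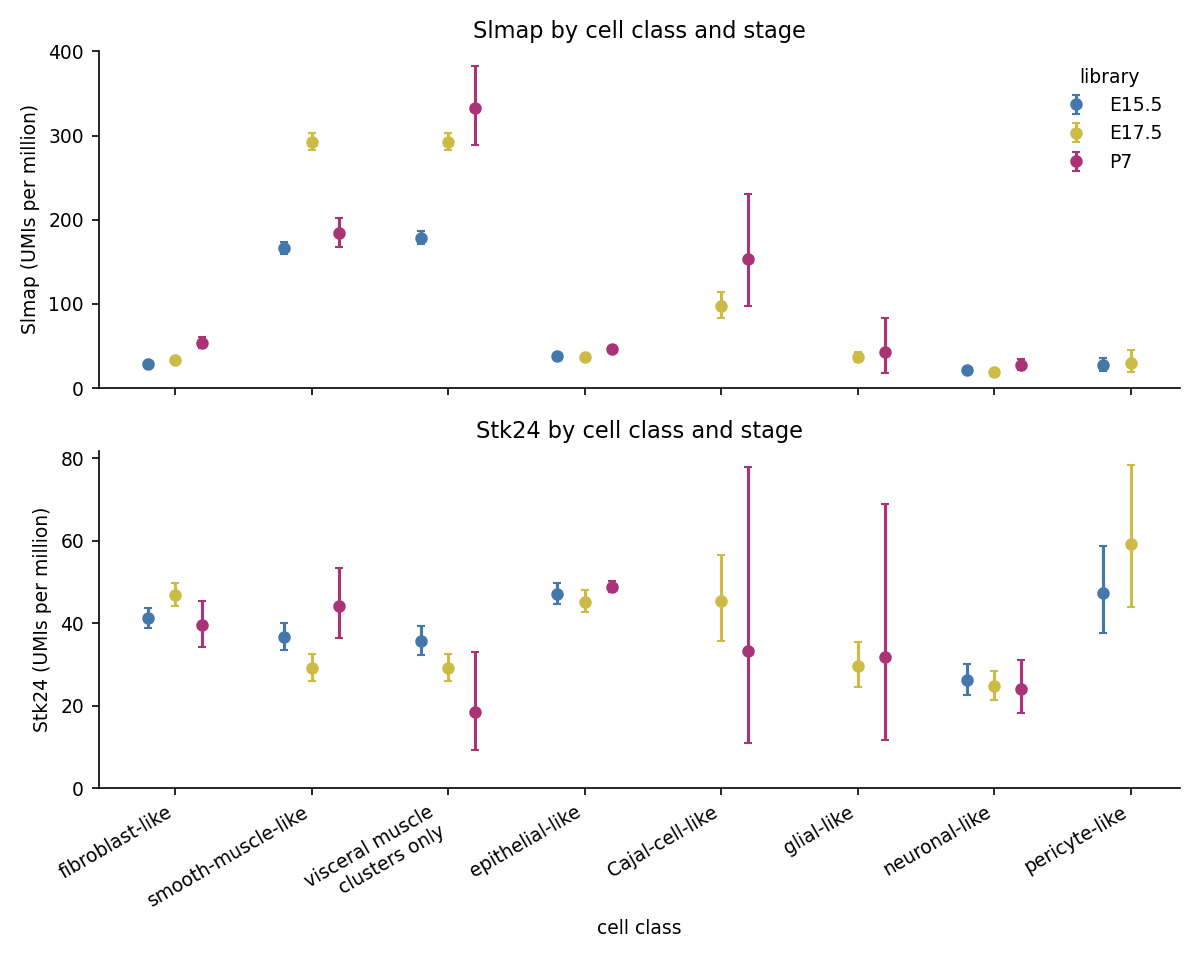
Slmap (top) and Stk24 (bottom) in CPM of each cell class (vertical axis) at E15.5, E17.5 and P7, with points for the class sum and bars for exact 95% Poisson intervals, which cover counting error only. Slmap in smooth-muscle-like cells stood at 167, 292 and 184 CPM, and in visceral muscle clusters at 178, 292 and 333 CPM.

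Fibroblast-like cells, the cells that lay down the connective tissue of the gut wall, had more RNA of the matrix list and less of the cell cycle list at E17.5 than at E15.5. Col6a5, a collagen VI chain, was at 11.2 and 283 CPM, and Dpt, a matrix protein that binds decorin, at 8.51 and 180.5 CPM. Cxcl2 and Cxcl5, chemokines that attract neutrophils, were at 8.26 and 221 CPM and at 4.66 and 102 CPM, with log2 ratios of 4.74 (4.55 to 4.93) and 4.46 (4.20 to 4.72). The other gene of the highest 5, Gm10260, is near-identical to Rps18, so its 1.48 and 163 CPM are uncertain. Among the lowest 5 were Idi1, Fdps, Hmgcs1 and Cyp51, enzymes of the pathway to cholesterol, with ratios of -2.73 (-2.88 to -2.57), -2.33 (-2.44 to -2.23), -2.04 (-2.14 to -1.95) and -2.03 (-2.14 to -1.93). The fifth was the replication-linked histone gene Hist1h2ap, at 862 and 216 CPM, whose reads can be shared with its near-identical copies.

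The extracellular matrix list had a median log2 ratio of 0.77 (0.75 to 0.84) in these cells, above each random list. Of its 26 measured members, 17 were at least 1.5-fold higher at E17.5 and 0 lower. At its ends were Fbln1 at 273 and 314 CPM and Fbn2 at 354 and 422 CPM, and Dcn (decorin) at 919.5 and 3673 CPM. The CD81 CD34 adventitial list, which marks fibroblasts around deep vessels and below crypts, stood at 2.63 (2.08 to 3.05), with 6 of 8 members higher, among them Clec3b at 0.388 and 9.80 CPM, while Rspo3 was at 62.3 and 50.7 CPM. Cell cycle genes had a median of -0.92 (-0.95 to -0.86), below each random list, and 27 of 30 members were at least 1.5-fold lower. The replication helicase genes Mcm5 and Mcm2 were at 71.6 and 26.6 CPM and 49.5 and 19.4 CPM, and Prc1 and Cenpe, which act in mitosis, at 185 and 131 CPM and 127 and 88.5 CPM. Dissociation and stress genes were higher in the same cells, with a median of 0.97 (0.94 to 0.99) and 11 of 16 members higher. Atf3 was at 48.9 and 233 CPM and Dusp1 at 36.9 and 166 CPM, while Hspa1a and Hspa1b were lower, at 386 and 283 CPM and 129 and 80.4 CPM.

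Signalling lists differed less at this step. STRIPAK complex members had a median of -0.34 (-0.37 to -0.26), with 0 of 18 at least 1.5-fold higher and 2 lower, Cttnbp2 being at 9.57 and 5.76 CPM. The Hippo core list holds the kinase cascade that restrains the co-activators YAP and TAZ. It also holds the genes of these co-activators, Yap1 and Wwtr1, and of their TEAD partners, so its median is not one of the kinases alone. That median was -0.13 (-0.20 to -0.08), with Tead2 at 140.3 and 87.4 CPM and Frmd6 at 19.8 and 24.6 CPM. YAP/TAZ targets had 0.21 (0.13 to 0.29), with Igfbp3 at 4.69 and 41.8 CPM and Foxf2 at 78.6 and 45.8 CPM. The Hedgehog response list, read from genes such as Gli1 that respond to epithelial Hedgehog ligands, stood at -0.15 (-0.18 to -0.11) with 0 of 8 members higher and 0 lower. Foxl1 was at 32.8 and 24.6 CPM and Hhip at 36.6 and 30.6 CPM. WNT ligands and modulators had a median of 0.35 (0.25 to 0.45), with 4 of 13 members higher, while Wnt5a was at 70.4 and 51.7 CPM. For BMP ligands and antagonists it was -0.16 (-0.27 to -0.03), with Bmp3 at 147 and 86.2 CPM and the antagonist Chrdl1 at 3.60 and 11.2 CPM. Imprinted growth genes had 0.21 (0.15 to 0.25), with Plagl1 at 155 and 234 CPM and Grb10 at 445 and 324 CPM. The PDGFRA-high subepithelial list, which marks the fibroblasts under the epithelium, had -0.23 (-0.31 to -0.15), with Bmp7 at 23.6 and 17.52 CPM and Sox6 at 9.39 and 13.7 CPM. Smooth muscle contractile genes had 0.37 (0.27 to 0.42), but 4 of 18 members passed the guard against free RNA, and their own median was -0.42. The median of all genes with 100 or more UMIs in both libraries was -0.13. Relative to it the Hedgehog response stood at -0.02, STRIPAK at -0.21 and the Hippo core at -0.005. These lists lay at percentiles 48.3, 3.05 and 50.1 of random lists.

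At P7, fibroblast-like cells had more of the CD81 CD34 adventitial and matrix genes than at E17.5 and less of the PDGFRA-high subepithelial genes. The highest ratios were those of Hmcn2, a large matrix protein, at 1.96 and 141 CPM, Fmo2, a flavin monooxygenase, at 6.36 and 175 CPM, and the interferon-induced Ifi27l2a at 27.6 and 697 CPM. With them were the matricellular gene Ccn3 at 4.68 and 113 CPM and Ccl21a, a chemokine of lymphoid stroma, at 4.36 and 141 CPM, the last from 12 of 1040 cells. Gm10260, again uncertain, was at least 274-fold lower, since P7 had 0 UMIs in these cells. The other 4 of the lowest 5 were Ccl2, which attracts monocytes, at 1073 and 36.7 CPM, Cwc22, a splicing factor, at 228 and 18.2 CPM, Cxcl13, which attracts B cells, at 949.7 and 87.3 CPM, and Id1, a target of BMP signalling, at 279 and 26.8 CPM. Another chemokine gene, Cxcl12, chosen after the results were seen, was at 324 and 1206 CPM. Ccl2 had a log2 ratio of -4.87 (-5.08 to -4.66) and Hmcn2 of 6.16 (5.75 to 6.61). RNA of enterocytes was present in the mesenchymal classes at P7, with Apoa4 at 300.4 CPM in fibroblast-like cells against 9928 CPM in epithelial-like cells.

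The CD81 CD34 adventitial list had a median of 3.10 (2.98 to 3.22) at this step, with 8 of 9 members at least 1.5-fold higher and 0 lower. Its ends held Pi16 at 0.680 and 17.2 CPM, the complement gene C3 at 1.20 and 30.6 CPM, and Rspo3, a WNT agonist, at 50.7 and 120.4 CPM. Extracellular matrix genes stood at 0.87 (0.85 to 0.91), above each random list, with 18 of 26 higher and 3 lower. Col15a1 was at 3.9998 and 46.4 CPM, Fbln2 at 7.16 and 58.2 CPM, Lox, the collagen cross-linking enzyme, at 223 and 126 CPM, and Col14a1 at 1186 and 703 CPM. PDGFRA-high subepithelial genes stood at -1.21 (-1.42 to -0.89), with 6 of 8 members lower, Nrg1 at 61.8 and 6.32 CPM and Bmp5 at 34.1 and 9.28 CPM. The clusters in the class differed too: at E17.5 cluster 7, with 598 cells, had Pdgfra, Bmp3, Nrg1 and Bmp4 among its leading genes. At P7 Pdgfra was among those of cluster 18 alone, with 89 cells, beside Dcn and Fibin and without Bmp3 or Nrg1. BMP ligands and antagonists had -0.58 (-0.71 to -0.21): Bmp3 was at 86.2 and 14.6 CPM, while the antagonist Grem1 was at 32.6 and 280.1 CPM. Imprinted growth genes were lower, at -0.77 (-0.85 to -0.65), with 7 of 12 members at least 1.5-fold lower and 3 higher, Dlk1 at 474 and 124 CPM, Cdkn1c at 1193 and 315 CPM and Peg3 at 532 and 1003 CPM. Cell cycle genes had -0.26 (-0.33 to -0.17), with 6 of 30 lower, Cenpe at 88.5 and 45.01 CPM and Mcm2 at 19.4 and 28.2 CPM.

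WNT ligands and modulators had a median of 0.47 (0.42 to 0.82), with Frzb at 1.48 and 16.2 CPM and Sfrp2 at 39.4 and 9.48 CPM, both secreted WNT antagonists. The Hedgehog response had 0.25 (0.14 to 0.34), with Hhip at 30.6 and 76.6 CPM and Foxl1 at 24.6 and 8.29 CPM. For the Hippo core the median was 0.34 (0.25 to 0.46), with Frmd6 at 24.6 and 54.5 CPM, and for YAP/TAZ targets 0.32 (0.20 to 0.49), with Nt5e at 0.920 and 8.29 CPM and Fjx1 at 99.5 and 25.7 CPM. STRIPAK complex members stood at 0.03 (-0.08 to 0.15), with Stk25 at 41.6 and 60.4 CPM, and this median was -0.13 when libraries were scaled by the median gene, whose log2 ratio was 0.16. Among random lists STRIPAK lay at percentile 19.2 and the Hippo core at 92.9. Dissociation and stress genes had 0.43 (0.39 to 0.48), with Fosb at 445 and 1067 CPM and Hspa1b at 80.4 and 21.5 CPM. Contractile genes had 1.06 (0.84 to 1.14), with Cald1 at 1146 and 724 CPM, but 4 of 18 members passed the guard against free RNA, with a median of 0.63. Cnn1, at 11.2 and 77.6 CPM, turned to a log2 ratio of -0.56 at clustering resolution 2.

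In smooth-muscle-like cells the contractile genes were higher and the cell cycle genes lower at E17.5 than at E15.5. The mix of the class differed: Dlk1 and Lsp1 were both among the leading genes of E15.5 clusters 6 and 17, with 528 and 188 of 1518 cells. At E17.5 this held for cluster 20, with 246 of 1334 cells. The values of this step in muscle therefore also hold a difference in mix. Smooth muscle contractile genes had a median log2 ratio of 0.90 (0.82 to 0.92), above each random list, with 15 of 18 at least 1.5-fold higher and 0 lower, and 0.79 (0.72 to 0.81) in visceral clusters alone. Most members of this list are also markers that name the class, and Actg2 and Des also select the visceral clusters. Des (desmin) was at 761 and 3103 CPM and Synm, which joins desmin filaments to the membrane, at 74.8 and 449 CPM, while Flna and Synpo2 were at 925 and 1064 CPM and 300.0 and 383 CPM. Cell cycle genes had a median of -1.48 (-1.57 to -1.44), with 30 of 30 members lower, and of -1.07 (-1.16 to -1.02) in visceral clusters. The visceral rule leaves out E15.5 cluster 17, whose 188 cells had Hist1h2ap, Top2a and Cenpf among their leading genes. It leaves out no E17.5 cluster, so the smaller fall follows from the rule and is no check on the larger one. Aurka was at 28.7 and 6.81 CPM, Plk1 at 31.6 and 8.07 CPM and Pcna at 132 and 67.4 CPM. The highest single genes were Ckm, the muscle creatine kinase, at 16.96 and 516 CPM, Myh7, a slow-type myosin heavy chain, at 5.81 and 116 CPM, and Ptgs2, the inducible cyclooxygenase, at 10.1 and 122 CPM. Cwc22, at 18.7 and 225 CPM, and the uncertain Gm10260 completed the 5. The lowest were Hist1h2ap, Birc5, a mitotic gene, at 145 and 38.98 CPM, the adhesion gene Alcam at 315 and 78.95 CPM, the transcription factor gene Zfhx3 at 127 and 34.3 CPM and the chemokine gene Cxcl12 at 132 and 36.2 CPM. Ckm had a ratio of 4.93 (4.73 to 5.13) and Alcam one of -1.996 (-2.10 to -1.89).

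The WNT, Hedgehog response and imprinted growth lists had negative medians in muscle at this step. WNT ligands and modulators had a median of -0.79 (-0.87 to -0.67), with 6 of 10 members lower and 0 higher, Dkk2 at 65.6 and 14.4 CPM and Sfrp2 at 117 and 42.7 CPM. The Hedgehog response had -0.74 (-0.91 to -0.61), with 5 of 7 lower, Gli1 at 21.3 and 8.16 CPM. Imprinted growth genes stood at -1.003 (-1.06 to -0.95), with Mest at 123 and 39.9 CPM and Dlk1 at 472 and 175 CPM, and PDGFRA-high subepithelial genes at -0.73 (-0.86 to -0.60), but at -0.01 over the 3 members that passed the guard against free RNA, with F3 (tissue factor) at 87.2 and 148 CPM. BMP ligands and antagonists had 0.13 (-0.18 to 0.33), with Grem1 at 294 and 385 CPM, and the CD81 CD34 adventitial list 0.01 (-0.28 to 0.16), from 4 members. YAP/TAZ targets had 0.06 (-0.12 to 0.21), with Ccn2 at 115 and 205 CPM, Axl at 19.3 and 12.6 CPM and a median of -0.11 over the 15 members that passed the guard against free RNA. STRIPAK complex members stood at -0.34 (-0.40 to -0.25), Slmap and Cttnbp2 being the highest and Stk26, a kinase related to Stk24, at 3.67 and 2.15 CPM. The Hippo core stood at -0.29 (-0.39 to -0.22), with Tead2 at 97.04 and 51.6 CPM. Extracellular matrix genes had -0.18 (-0.22 to -0.15), with Col15a1 at 4.81 and 26.3 CPM and Fbln2 at 2.90 and 0.717 CPM. Dissociation and stress genes had 0.89 (0.84 to 0.94), with 12 of 16 higher, Dusp1 at 60.6 and 258 CPM and Atf3 at 63.8 and 268 CPM. The median gene stood at -0.28, and relative to it the matrix list turned to 0.10, the STRIPAK list stood at -0.06, the Hippo core at -0.009 and Stk24 at -0.05. Among random lists STRIPAK lay at percentile 35.2 and the Hippo core at 62.35.

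The smooth-muscle-like cells of P7 lay in other clusters than those of E17.5, so the values of this step hold the difference between clusters 11, 19 and 25 at P7 and clusters 3, 20, 25 and 27 at E17.5. Eln, the elastic fibre protein, was at 29.4 and 4815 CPM and led clusters 11 and 25, and in the visceral clusters it was at 29.4 and 91.98 CPM. The highest ratios by the naming rule were those of Inpp4b, a phosphoinositide phosphatase, at 0.538 and 454 CPM, Map3k7cl at 0.358 and 199.9 CPM and the connexin gene Gja4 at 0.179 and 129 CPM. The next were Olfml2a at 0.269 and 124 CPM and the transcriptional corepressor gene Cbfa2t3 at 0.627 and 282 CPM. In the visceral cluster of P7 Map3k7cl had 1 UMI and Inpp4b, Gja4, Olfml2a and Cbfa2t3 had 0. Olfml2a had 3 UMIs at E17.5 and a log2 ratio of 8.85 (7.29 to 11.13), and Gja4 had 2 UMIs and an interval from 7.63 to 12.55. Gm10260 was at least 114-fold lower, against 0 UMIs. With it among the lowest 5 were the imprinted RNA H19 at 495 and 14.8 CPM, the cytokine gene Il17b at 149 and 5.59 CPM, Myh7 at 116 and 5.59 CPM and Igfbp2, which binds insulin-like growth factors, at 506 and 34.7 CPM. In the visceral clusters the ratios of H19 and Igfbp2 were -4.51 and -2.01.

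Contractile genes had a median of -0.53 (-0.58 to -0.48) in all smooth-muscle-like cells, with 8 of 18 lower and 2 higher, and 0.16 (0.14 to 0.22) in visceral clusters, where 5 were higher and 1 lower. The visceral clusters were chosen by Actg2 and Des, members of this list. A higher contractile median there is therefore partly set by the choice and is no independent result. Actg2 was at 21609 and 3836 CPM and Cnn1 (calponin) at 2266 and 763 CPM, while Lmod1 (leiomodin) was at 441 and 679.5 CPM. Cell cycle genes had 0.58 (0.43 to 0.67), Prc1 being at 52.96 and 126 CPM, but 0.15 (-0.09 to 0.34) in visceral clusters and -0.59 with the 3 libraries clustered together. Dissociation and stress genes were also higher in the class, at 1.18 (1.15 to 1.22), with Fosb at 214 and 1209 CPM and Hspb1 at 1763 and 508 CPM, and lower in visceral clusters, at -0.44 (-0.61 to -0.34). Extracellular matrix genes had 0.26 (0.19 to 0.33), with Loxl1, a cross-linking enzyme of elastic fibres, at 10.4 and 94.6 CPM and Fbn2 at 224 and 82.6 CPM. The matrix median was 0.13 over the 14 members that passed the guard against free RNA. In visceral clusters it was 0.41 (0.26 to 0.54), but -0.003 over the 11 members that passed there. STRIPAK complex members had 0.26 (0.12 to 0.46), with Stk25 at 34.95 and 60.6 CPM. The matrix and STRIPAK lists both stood at -0.01 relative to the median gene, whose ratio was 0.26.

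Imprinted growth genes had a median of -1.62 (-1.82 to -1.43) in the class and -1.29 (-1.52 to -0.9998) in visceral clusters, with 9 of 12 members lower and Sgce at 33.97 and 66.6 CPM. WNT ligands and modulators stood at -1.76 (-2.15 to -1.30) and -0.43 (-0.87 to -0.03), Sfrp1 being at 112 and 9.18 CPM and Rspo3 at 205 and 33.1 CPM. The Hedgehog response stood at -0.46 (-0.88 to -0.19) and -0.74 (-1.03 to -0.47), with Ptch1, the Hedgehog receptor, at 91.4 and 42.3 CPM and Hhip at 39.3 and 1.995 CPM. BMP ligands and antagonists had -0.74 (-1.21 to -0.37) in the class, the antagonist Nog (noggin) being at 39.5 and 2.79 CPM and the ligand Bmp2 at 1.97 and 56.7 CPM. Their median was -1.16 over the 8 members that passed the guard, -0.49 (-0.69 to -0.11) in visceral clusters and 0.01 with the 3 libraries clustered together. PDGFRA-high subepithelial genes had -1.49 (-1.76 to -1.11) in the class and -0.87 over the 4 members that passed the guard, with F3 at 148 and 25.9 CPM, and -0.49 (-0.68 to -0.09) in visceral clusters. The CD81 CD34 adventitial list had -0.68 (-1.38 to -0.60) over 4 members and -1.58 over the 3 that passed the guard, but 0.53 (0.40 to 0.65) in visceral clusters. Its member Grem1 was at 385 and 128 CPM in the class and at 385 and 528 CPM in visceral clusters. The Hippo core had 0.52 (0.34 to 0.59), with Frmd6 at 18.7 and 57.1 CPM, and lay at percentile 87.5 of random lists. YAP/TAZ targets had 0.43 (0.20 to 0.53) and in visceral clusters 0.07 (-0.25 to 0.33), Tgfb2 at 9.68 and 225 CPM in the class having a ratio of -0.21 there.

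**Figure D2:**
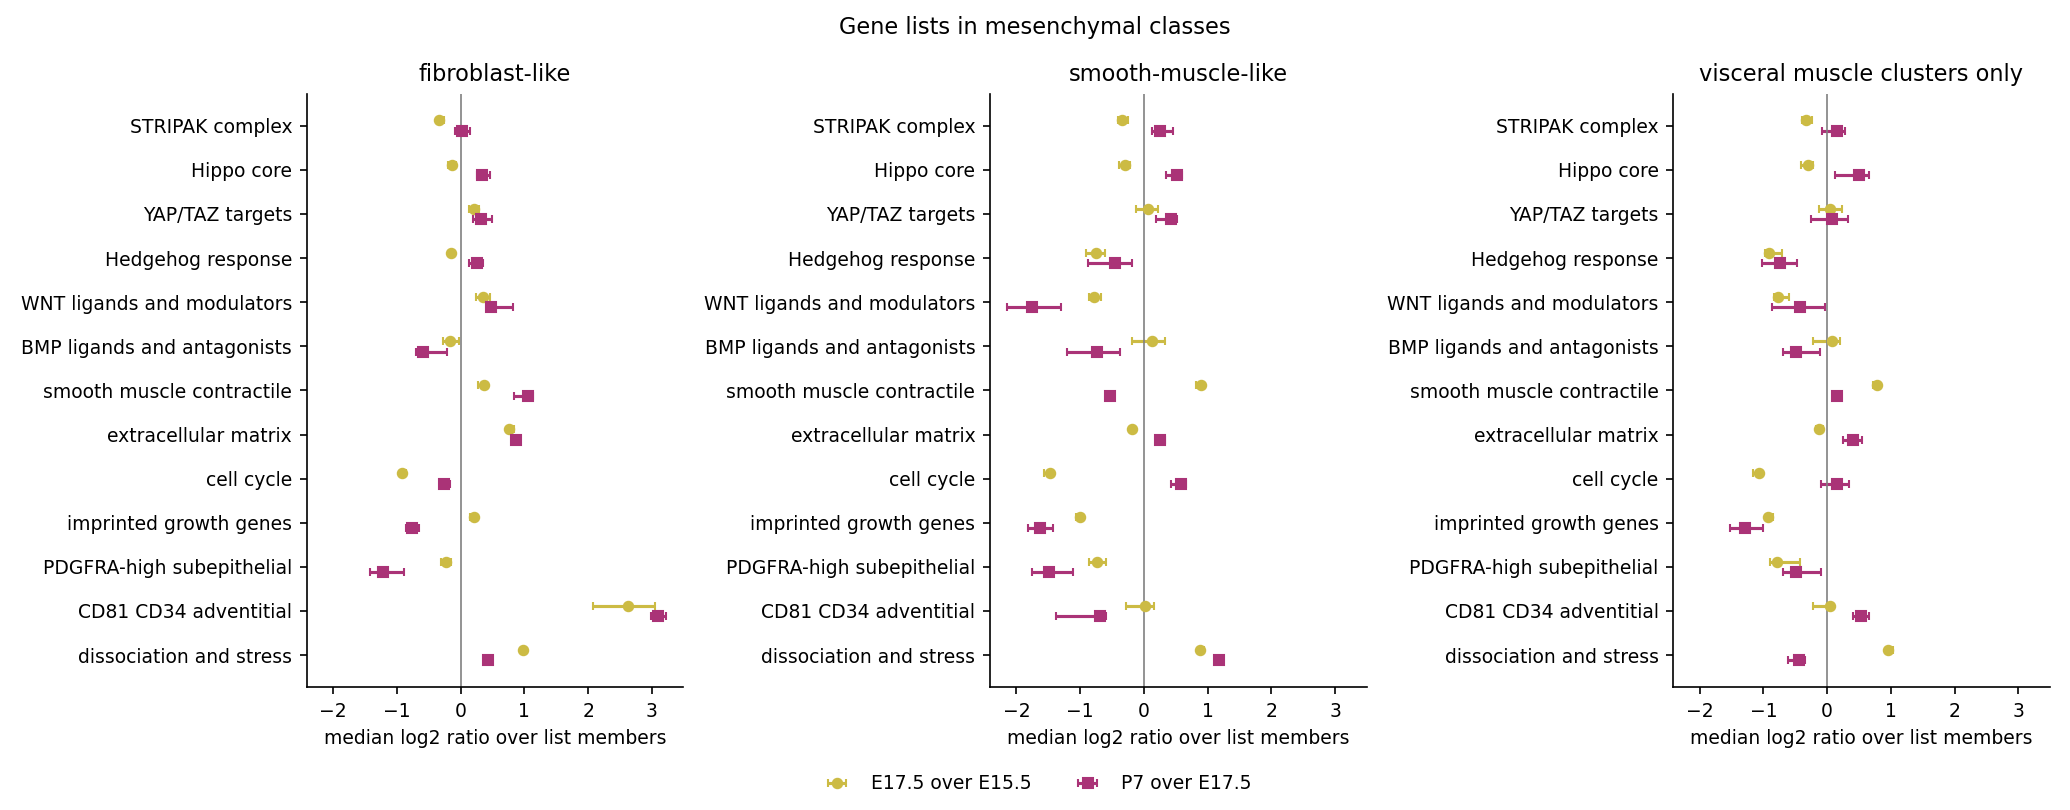
Median log2 ratio of each mesenchymal gene list (horizontal axis) in fibroblast-like cells, smooth-muscle-like cells and visceral muscle clusters, for E17.5 over E15.5 and P7 over E17.5, with bars for intervals from 1000 Poisson redraws. Contractile genes stood at 0.90 and -0.53 in smooth-muscle-like cells and at 0.79 and 0.16 in visceral clusters, and the CD81 CD34 adventitial list at 2.63 and 3.10 in fibroblast-like cells.

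Epithelial-like cells of E17.5, in clusters 8, 13, 17, 19, 26 and 29, had more RNA of absorptive, goblet and enteroendocrine genes than those of E15.5, in clusters 5, 8, 20, 23 and 26. Goblet genes had a median log2 ratio of 2.34 (2.30 to 2.38), with 9 of 9 members at least 1.5-fold higher, the mucin Muc2 at 12.2 and 135 CPM and Zg16, a mucus lectin, at 5.71 and 55.1 CPM. Enteroendocrine genes had 1.52 (1.48 to 1.57), with 12 of 13 higher, Neurod1 at 16.8 and 25.7 CPM, and the progenitor factor Neurog3 at a ratio of -0.11 (-0.29 to 0.08). The mix of the class differed: cluster 26 of E17.5, with 117 of 1560 cells, was led by Sct, Cck and Chgb, and no E15.5 cluster had Cck or Chgb among its leading genes. The cluster led by Tff3, Agr2, Spink4 and Fcgbp held 258 cells at E17.5 and also had Sct among its leading genes. At E15.5 these 4 goblet genes were among those of cluster 20, with 154 of 1294 cells. Sct was the first leading gene of cluster 20, so enteroendocrine and goblet genes were not split between clusters there. Gip, an incretin hormone, was at 1.09 and 408 CPM, with 99.1% of its E17.5 UMIs in the 22 cells that held 10 or more, Sst (somatostatin) at 5.04 and 328 CPM, with 99.6% in 11 such cells, and Nts (neurotensin) at 82.8 CPM against 0 UMIs at E15.5. The insulin genes Ins2 and Ins1 stood among the highest 5, at 177 and 126 CPM, but 98.9% of the 7505 insulin UMIs of that library came from 1 cell. Ins1 had no count in the whole E15.5 and P7 libraries, so no fold is given for it. Gm10260, the other gene of the highest 5, was at 2.29 and 214 CPM.

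The lipid absorption list had a median of 1.41 (1.35 to 1.47), above each random list, with 15 of 18 members higher and 1 lower. The mix of the class differed here too, and the medians hold that difference. Fabp2 and Rbp2 were both among the leading genes of cluster 23 at E15.5, with 114 of 1294 cells. At E17.5 they were among those of clusters 13 and 29, with 297 and 64 of 1560 cells. Rbp2, the retinol carrier of enterocytes, was at 237 and 2490.2 CPM, Apoa4, an apolipoprotein of chylomicrons, at 158 and 1599.5 CPM, and the lipoprotein receptor gene Scarb1 at 16.7 and 10.97 CPM. Brush border and digestion genes had 1.08 (0.95 to 1.13), with 11 of 16 higher, sucrase-isomaltase (Sis) at 0.811 and 14.3 CPM, the amino acid transporter Slc6a19 at 4.44 and 25.4 CPM and Dpp4 at 97.8 and 85.8 CPM. Suckling enterocyte genes had 0.89 (0.78 to 1.002), with lactase (Lct) at 19.6 and 89.2 CPM and Fcgrt, the receptor that takes up maternal antibody, at 35.9 and 191 CPM, while the endocytic receptor gene Lrp2 was at 9.27 and 3.41 CPM. Crypt stem genes had 0.70 (0.49 to 0.86), but 0.28 over the 7 members that passed the guard against free RNA. Olfm4 was at 4.72 and 63.7 CPM, but Axin2 at 13.5 and 9.59 CPM and Ascl2 at 12.7 and 8.94 CPM. Antimicrobial and mucosal defence genes stood at 0.77 (0.72 to 1.06), with Pigr, the transporter of secretory antibody, at 1.83 and 48.8 CPM.

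The lowest ratios at this step belonged to Tfrc, the transferrin receptor, at 226 and 59.9 CPM, and S100a6 at 787 and 228 CPM, followed by Marcksl1 at 144 and 48.1 CPM, the mitochondrial carrier gene Slc25a4 at 393 and 138 CPM and the metallothionein Mt2 at 282 and 101 CPM. Fetal epithelium genes had a median of -3.10 (-3.54 to -2.73), with 6 of 6 members lower, and of -4.57 over the 5 members that passed the guard against free RNA, the RNA-binding proteins Igf2bp1 and Lin28b at 104 and 42.4 CPM and 2.29 and 0.772 CPM. Spp1, with a ratio of -8.52 (-10.40 to -7.16), had 97.8% of its E15.5 UMIs in the 25 cells of cluster 26. With the 3 libraries clustered together, 23 of these cells fell in the cluster led by genes of pancreatic enzymes. Cell cycle genes had -0.37 (-0.46 to -0.33), with 10 of 30 lower, Mcm4 at 70.9 and 36.4 CPM and Nusap1 at 50.5 and 58.8 CPM. Imprinted growth genes had -0.56 (-0.70 to -0.39), with Peg3 at 126 and 55.5 CPM and Cdkn1c at 760.4 and 951 CPM. Epithelial signals had a median of -0.10 (-0.34 to -0.01), which turned to 0.03 relative to the median gene (-0.13). Over the 5 members that passed the guard against free RNA it was -0.45. The Hedgehog ligand Shh was at 22.8 and 2.76 CPM and Wnt3 at 0.564 and 2.89 CPM. STRIPAK complex members had -0.14 (-0.20 to -0.09), the Hippo core -0.25 (-0.34 to -0.16), with Taok3 at 78.7 and 104 CPM, and YAP/TAZ targets 0.03 (-0.09 to 0.21), although 6 of 18 targets passed the guard against free RNA. Relative to the median gene STRIPAK stood at -0.006 and the Hippo core at -0.12, at percentiles 48.4 and 10.8 of random lists. Dissociation and stress genes had 0.58 (0.47 to 0.66), with Hsp90aa1 at 1349.8 and 763 CPM, but 2 of 16 passed the guard, with a median of -0.43.

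At P7, when pups drink milk, epithelial-like cells, in clusters 1 to 8, 10, 13 to 16, 23 and 26, had more RNA of suckling, lipid absorption and defence genes than at E17.5. Suckling enterocyte genes had a median of 1.70 (1.64 to 1.77), with 9 of 10 at least 1.5-fold higher and the lysosomal proteases Ctsl and Lgmn at 115 and 2261 CPM and 20.2 and 589.8 CPM. Lipid absorption genes had 1.26 (1.21 to 1.28), with 14 of 18 higher, Apoa4 at 1599.5 and 9928 CPM and Apob at 265 and 966 CPM. Fabp2 and Rbp2 were both among the leading genes of clusters 13 and 29 at E17.5, with 297 and 64 of 1560 cells. At P7 this held for clusters 2, 3, 8, 10 and 14, with 624, 618, 463, 444 and 302 of 6047. The medians of this class therefore also hold a difference in its mix. Brush border and digestion genes had 1.15 (1.09 to 1.25), with Cdhr5, a microvillus cadherin, at 137 and 661 CPM but Sis at 14.3 and 10.8 CPM. The same list holds Treh (trehalase), at 1.15 CPM at P7 and with no count in the whole E17.5 library. Antimicrobial and mucosal defence genes had 2.18 (2.13 to 2.21), above each random list, with the bactericidal lectins Reg3b and Reg3g at 5.61 and 130.2 CPM and 2.28 and 31.6 CPM. Among single genes the highest were Paneth cell products, Defa30 at 0.325 and 253 CPM, the lectin Itln1 at 0.325 and 127 CPM and Defa35 at 110 CPM, the last with no count in the whole E17.5 library. The next were 2210407C18Rik at 1.504 and 129.6 CPM and the milk-clotting protease Cym at 26.5 and 911 CPM. Defensin genes are near-identical copies that can share reads, and 97.4% of the Defa30 UMIs lay in the 122 of 6047 cells that held 10 or more. Cluster 23, led by defensin genes, held 42 cells.

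Crypt stem genes had a median of 0.93 (0.82 to 1.14) at P7 against E17.5, with 7 of 9 higher, Olfm4 at 63.7 and 922 CPM and Axin2, a target of WNT signalling, at 9.59 and 34.3 CPM. Enteroendocrine genes stood at -0.74 (-0.76 to -0.71), with 7 of 13 lower and 2 higher. The mix of the class differed as well, since the cluster led by enteroendocrine genes held 117 of 1560 cells at E17.5 and 252 of 6047 at P7. The hormone genes ghrelin (Ghrl) and secretin (Sct) were at 528 and 60.3 CPM and 1336 and 331 CPM, but Pyy and Nts at 67.4 and 218 CPM and 82.8 and 233 CPM. Goblet genes had -0.47 (-0.48 to -0.44), with Agr2 at 1452 and 752 CPM and Muc2 at 135 and 345 CPM. Clusters with Tff3, Agr2, Spink4 and Fcgbp among their leading genes held 258 of 1560 cells at E17.5 and, as clusters 5 and 16, 530 and 196 of 6047 at P7. Cell cycle genes had -0.62 (-0.67 to -0.59), with 18 of 30 lower, Birc5 at 210.1 and 85.2 CPM and Rrm2 at 37.6 and 14.7 CPM. Imprinted growth genes had -2.28 (-2.47 to -2.04), with 10 of 12 lower, H19 at 1548 and 111 CPM and Igf2r, which clears the growth factor IGF2, at 77.5 and 100.1 CPM. Jaml, an adhesion gene, was at 216 and 3.81 CPM and H2-Q10, a secreted class I gene with close paralogs, at 132 and 5.20 CPM, and both were among the lowest 5 with Ins1, Ins2 and Gm10260.

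Fetal epithelium genes had a median of -0.07 (-0.73 to 0.75), but 1.78 over the 4 members that passed the guard, with Igf2bp1 at 42.4 and 7.40 CPM. At P7 93.9% of the Spp1 UMIs and 83.8% of the Clu UMIs lay in the 33 cells of cluster 26, of which 31 fell in the cluster led by pancreatic enzyme genes when the libraries were clustered together. It is therefore open whether the Spp1 and Clu values of either step describe intestinal epithelium. Epithelial signals had 0.31 (0.12 to 0.39), with a median of -0.01 over the 4 members that passed the guard, Shh at 2.76 and 0.228 CPM, Ihh at 41.4 and 31.2 CPM and Wnt3 at 2.89 and 9.06 CPM. STRIPAK complex members had 0.07 (0.00 to 0.12), with Strip2 at 0.406 and 1.75 CPM and Mob4 at 114 and 89.5 CPM, and the Hippo core 0.15 (0.09 to 0.20), with Wwc1 at 42.7 and 66.5 CPM. The STRIPAK and Hippo medians lay at percentiles 52.0 and 71.1 of random lists. YAP/TAZ targets had -0.60 (-0.69 to -0.14), but 3 of 19 passed the guard against free RNA, with a median of 1.503, Gadd45a being at 21.5 and 60.8 CPM and Nuak2 at 5.08 and 18.99 CPM. Dissociation and stress genes had 1.17 (1.12 to 1.22), with 4 of 16 passing the guard and Atf3 at 25.1 and 223 CPM. Under the stricter cell filter the lipid absorption median was 0.79 and the cell cycle median -0.32.

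**Figure D3:**
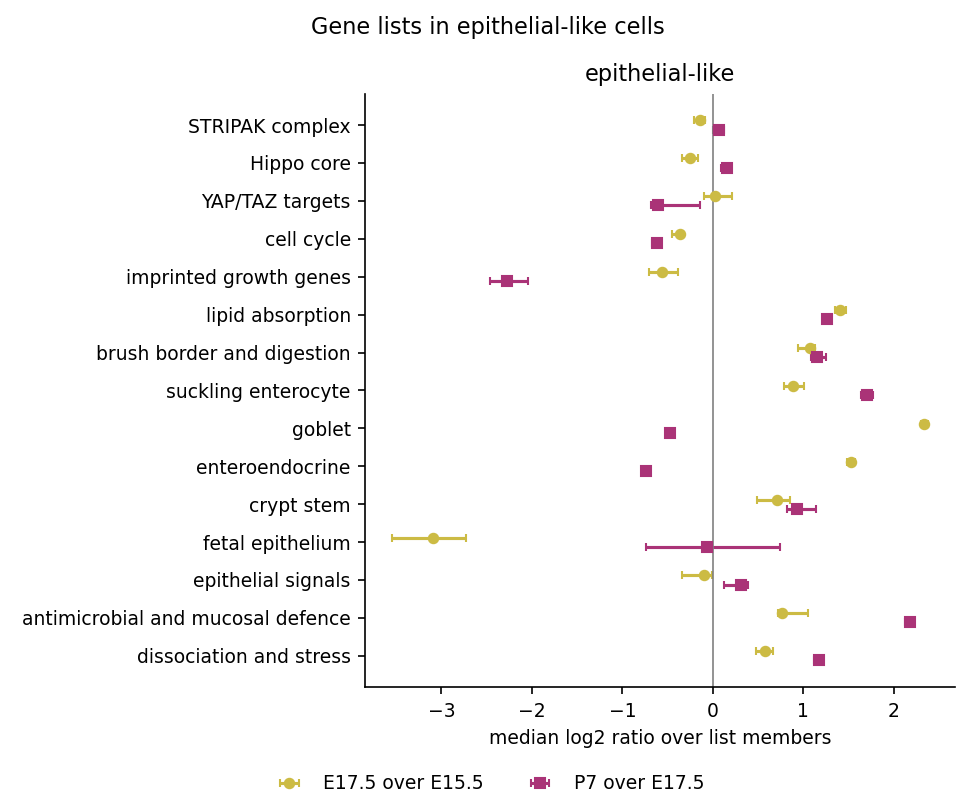
Median log2 ratio of each gene list in epithelial-like cells (horizontal axis) for E17.5 over E15.5 and P7 over E17.5, with bars for intervals from 1000 Poisson redraws. Lipid absorption genes stood at 1.41 and 1.26, goblet genes at 2.34 and -0.47, and imprinted growth genes at -0.56 and -2.28.

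Cells in cycle were compared after thinning every cell to 2000 UMIs, since depth differed between libraries. Fibroblast-like cells with 2 or more cell cycle UMIs made up 65.8% (64.1 to 67.4%) at E15.5, 37.1% (35.6 to 38.5%) at E17.5 and 29.0% (26.2 to 31.9%) at P7, and the list held 4000, 2209 and 1831 CPM of their RNA. In epithelial-like cells the shares were 69.5% (66.9 to 72.0%), 52.1% (49.5 to 54.6%) and 35.3% (34.1 to 36.6%), and in smooth-muscle-like cells 48.6% (46.1 to 51.2%), 21.6% (19.5 to 24.0%) and 22.8% (19.3 to 26.5%). Visceral muscle clusters gave 43.5%, 21.6% and 18.8% (11.2 to 28.8%), the last from 85 cells. The E15.5 share leaves out cluster 17, which had cell cycle genes among its leading genes. Neuronal-like cells, most of which should not divide, gave 10.3%, 11.3% and 5.17% at median depths of 9398, 7540 and 12825.5 UMIs, against 7749, 5170 and 4591.5 UMIs in fibroblast-like cells. Without thinning the shares were 86.5%, 60.4% and 46.7% in fibroblast-like cells, 96.1%, 83.9% and 81.2% in epithelial-like cells, 77.5%, 51.0% and 31.8% in smooth-muscle-like cells and 62.1%, 47.2% and 58.5% in neuronal-like cells. Thinning left out 24, 166 and 33 fibroblast-like cells, 15, 20 and 82 epithelial-like cells, 17, 8 and 12 smooth-muscle-like cells and 8, 5 and 2 neuronal-like cells that were shallower.

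**Figure D4:**
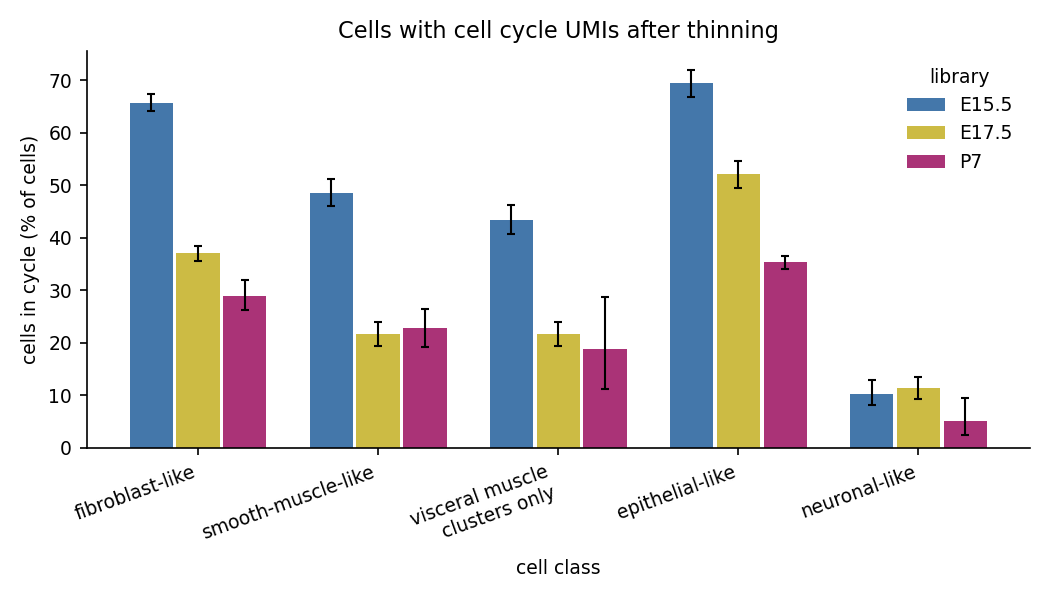
Share of cells with 2 or more cell cycle UMIs after thinning to 2000 UMIs (vertical axis, percent of cells) by class and library, with bars for the share and lines for exact 95% Clopper-Pearson intervals. Fibroblast-like cells stood at 65.8%, 37.1% and 29.0%, and neuronal-like cells at 10.3%, 11.3% and 5.17%.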

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

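The visceral clusters as an alternative and the list of pancreatic enzyme genes were chosen only after the results were seen. The CD81 CD34 adventitial list stood out because its 2 classes went opposite ways at P7 against E17.5, with a median log2 ratio of 3.10 in fibroblast-like cells and -0.68 in smooth-muscle-like cells, the latter over 4 members. The difference between the classes was not tested. In visceral clusters the muscle value was 0.53, with no UMI minimum it was 0.27, and over the 3 members that passed the guard against free RNA it was -1.58.

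Among clusters left out of the comparisons, 63 cells of E15.5 cluster 24 (0.768% of kept cells) and 20 cells of P7 cluster 27 (0.2499%) were led by genes of pancreatic enzymes. With the 3 libraries clustered together, the cluster led by these genes held 87 cells at E15.5, 1 at E17.5 and 53 at P7. It took in 23 of the 25 cells of E15.5 cluster 26 and 31 of the 33 cells of P7 cluster 26, the epithelial-like clusters led by Spp1, where Ctrb1 stood at 110.4 and 54.5 CPM. A count of 0 would have allowed 0.0366% and 0.0375%. Ctrb1 stood at 29616 and 187106 CPM in these clusters, Clps at 10700 and 60634 CPM, Pnliprp1 at 10904 and 46546 CPM and Cpa1 at 4132 and 10675 CPM.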

How the results depend on the processing

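The visceral clusters and the members that passed the guard against free RNA were chosen as alternatives only after the results were seen, and the other settings were fixed before. No paired analysis was possible because each stage is 1 library. For the main results of the comparisons, 412 values stayed within their counting interval, 115 moved outside it, and 2 turned direction from a ratio of at least 1.5-fold. For single genes and other lists these counts were 3482, 720 and 13. Having no cell filter left all 500 values unchanged, since the filter removed 0 cells. Of these values 61 are counted in the 412 and 439 in the 3482, and they are no check on the results. Of the 3 simulated classes, smooth-muscle-like cells at P7 had the lowest share of genes changed 1.5-fold with an interval on the right side of 0, at 69.1%. Classes that were not simulated were shallower there: 3 UMIs are 20.02 CPM in cells resembling interstitial cells of Cajal, 15.9 CPM in glial-like cells and 5.02 CPM in visceral clusters, against 1.20 CPM in smooth-muscle-like cells.

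In the visceral clusters alone, Slmap in muscle at P7 over E17.5 turned to 0.19 and Stk24 to -0.66. So did Atf3 (-0.0932), Foxf2 (0.56), Grem1 (0.46), Lum (0.26), Nkx2-3 (-1.10), Tgfb2 (-0.21), the CD81 CD34 adventitial median (0.53) and the dissociation and stress median (-0.44). This alternative keeps 1 of the 3 muscle clusters of P7, so its construction shows the cause of these turns: other cells were counted. It also moved the contractile medians to 0.79 and 0.16, the latter across 0, and the cell cycle medians to -1.07 and 0.15 at the 2 steps. The contractile list holds Actg2 and Des, by which the visceral clusters were chosen, so its shift at P7 is partly set by that choice. The visceral alternative drops E15.5 cluster 17, with Top2a, Cenpf and Prc1 among its leading genes, and no E17.5 cluster. The shifts at the first step therefore follow from its construction. Slmap stood at 178 CPM at E15.5 and 333 CPM at P7, with a ratio of 0.71 at the first step, and Stk24 at 18.4 CPM at P7. The muscle shares of non-epithelial cells were 19.2% at E15.5 and 4.45% at P7, and the shares in cycle 43.5% and 18.8%.

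With the 3 libraries clustered together, muscle at P7 over E17.5 had Prc1 turned to -0.48, the BMP median to 0.0108 and the cell cycle median to -0.59, and the contractile median was -0.47. At E17.5 over E15.5 the muscle values were 0.68 for Slmap, 0.76 for contractile genes and -1.11 for the cell cycle, with Slmap at 182 CPM at E15.5. Muscle made up 18.2% of non-epithelial cells at E15.5, and 42.8% and 15.9% of muscle cells were in cycle at E15.5 and P7. The fibroblast-like share at E17.5 was 49.99%, their cell cycle median at the first step -0.99 and the epithelial lipid absorption median at P7 1.28. Joint clusters 21 and 32, with 502 and 214 cells, had Prc1 and Top2a among their leading genes. Both stayed unnamed because smooth muscle and another class lay within 1 log2 unit. Muscle held 1261 cells at E15.5 and 519 at P7 under this setting, against 1518 and 548. Whether dividing muscle cells left the class this way was not tested, nor was any other cause.

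At resolution 0.5, fibroblast-like shares were 46.95% at E15.5 and 50.2% at E17.5, and the first step gave -0.20 for the Hedgehog response and -1.01 for the cell cycle in these cells. Muscle made up 28.1% at E15.5 with Slmap at 149 CPM, and its first step gave 0.97 for Slmap, 1.08 for contractile genes and -1.37 for the cell cycle. At resolution 2, Cnn1 in fibroblast-like cells at P7 turned to -0.56, Slmap was at 42.98 CPM with a ratio of 0.36, and the share was 44.9%. The P7 medians there were 0.11 for the Hedgehog response, 0.94 for matrix and -0.0734 for the cell cycle. The cause was not tested at either resolution.

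Under the stricter cell filter, epithelial-like cells at P7 had Slmap at 43.4 CPM, Stk24 at 51.3 CPM, 42.8% of cells in cycle, a cell cycle median of -0.32 and lipid absorption medians of 1.27 and 0.79 at the 2 steps. The fibroblast-like share at E17.5 was 49.3% and their cell cycle median at the first step -0.98. Without doublet removal the lipid absorption medians were 1.34 and 1.36. With the mean of each cell's own CPM they were 1.27 and 1.13, the cell cycle medians -0.99 in fibroblast-like cells and -1.61 in muscle at the first step and -0.56 in epithelial-like cells at the second, the contractile medians in muscle 0.92 and -0.60, and the fibroblast matrix median at P7 0.83. The cause was not tested for these 3 settings.

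Scaling by the median ratio adds 1 constant to every log2 ratio of a class and step, which shows the cause of its shifts. In fibroblast-like cells at the first step it gave 0.32 for Stk24, -0.21 for STRIPAK, -0.0165 for the Hedgehog response, 0.89 for matrix and -0.79 for the cell cycle. At P7 these lists stood at -0.13, 0.0935, 0.71 and -0.42, so STRIPAK changed side of 0. In muscle the first step gave 1.09 for Slmap, -0.0518 for Stk24, 1.18 for contractile genes and -1.19 for the cell cycle, and the second -0.93 for Slmap, -0.80 and 0.31. In epithelial-like cells the first step gave 0.0669 for Slmap and 0.072 for Stk24, both across 0, -0.23 for the cell cycle and 1.54 for lipid absorption. Totals without the most abundant genes gave, in fibroblast-like cells, -0.0885 for the Hedgehog response and -0.86 for the cell cycle at the first step, and -0.0868 for STRIPAK, 0.76 for matrix and -0.37 for the cell cycle at P7. In muscle they gave 0.94 and -0.89 for Slmap, 1.03 and -0.75 for contractile genes and -1.35 and 0.36 for the cell cycle at the 2 steps.

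Over members that passed the guard against free RNA, the epithelial YAP/TAZ median at P7 turned to 1.503, from fewer members. With no UMI minimum the CD81 CD34 adventitial median in muscle at P7 turned to 0.27, from more members.

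Shares of cells in cycle are given at E15.5, E17.5 and P7. Thinned to 1000 UMIs they were 51.02%, 25.4% and 18.5% in fibroblast-like cells, 37.9%, 14.4% and 15.2% in muscle and 52.3%, 38.4% and 24.9% in epithelial-like cells. With 4 or more UMIs required they were 49.5%, 22.3% and 15.99%, 35.1%, 11.8% and 12.7%, and 51.2%, 37.01% and 22.9% in the same order. Not thinned they were 86.5%, 60.4% and 46.7%, 77.5%, 51.05% and 31.8%, and 96.1%, 83.9% and 81.2%. Fewer UMIs or a higher bar lower each share by construction.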

Other observations

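The test of the muscle clusters, the test of Epcam RNA in muscle and the tests of the levels and spread of Gm10260 and Cwc22 over classes were chosen only after the results were seen, as were the genes named in this part. In neuronal-like cells at E17.5 and P7, Vip, a relaxing neuropeptide, was at 842 and 3377 CPM, Nos1, which makes nitric oxide, at 155 and 843 CPM, the synaptic gene Snap25 at 180 and 548 CPM and Chat, which makes acetylcholine, at 15.8 and 26.5 CPM. The neuropeptide gene Gal was at 607 CPM at E15.5 and 1071 CPM at E17.5.

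Glial-like cells at E17.5 and P7 had the cadherin gene Cdh19 at 36.6 and 153 CPM, the P7 value from 66 cells that held Epcam at 122 CPM, against 7.95 CPM at E17.5. Cells resembling interstitial cells of Cajal had Kit at 627 and 1742 CPM, Ano1, the chloride channel of pacemaking, at 129 and 467 CPM and Prkcq at 87.0 and 400 CPM, the P7 values from 34 cells. Their Epcam stood at 13.7 and 614 CPM, against 2262 CPM in epithelial-like cells at P7, so these P7 cells carried epithelial RNA. A single epithelial-like cell of E17.5 held 3097 Ins1 UMIs, 4327 Ins2 UMIs and 427 UMIs of Iapp, which beta cells secrete with insulin.

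Slmap was lower in smooth-muscle-like cells at P7 than at E17.5, with a log2 ratio of -0.67. Free RNA from epithelial cells as a diluent was argued against, since Epcam in these cells stood at 5.04% of its epithelial level. In visceral clusters alone, where Cym stood at 293 CPM against 911 CPM in epithelial-like cells, the ratio was 0.187, so the lower class value may come from the mix of muscle clusters in the class. Whether age, dissection or sort set that mix stays open, since each stage is 1 library.

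Genes of sterol synthesis were lower in fibroblast-like cells at E17.5 than at E15.5, with a median log2 ratio of -1.76 over 16 genes chosen after Idi1, Fdps, Hmgcs1 and Cyp51 had been seen and leaving these 4 out. Epithelial free RNA at E15.5 was argued against, since the genes stood at a median of 56.5% of their epithelial level in fibroblast-like cells, and so was the scaling, since the median was -1.63 under median-ratio scaling. The medians were -0.84 in smooth-muscle-like, -0.56 in epithelial-like and -0.27 (-0.32 to -0.12) in neuronal-like cells, so a difference between the libraries that lowers these genes in every class cannot be told apart from one of stage. At P7 against E17.5 the medians were 1.20 in fibroblast-like, 0.36 in smooth-muscle-like, 0.69 in neuronal-like and -0.87 in epithelial-like cells, where 11 of 16 genes were at least 1.5-fold lower. A biological difference between the stages stays open and untested.

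Gm10260 and Cwc22 were higher at E17.5 than at E15.5 in fibroblast-like, smooth-muscle-like, epithelial-like and neuronal-like cells. Free RNA from another of these classes was argued against, since each class held at least 54.3% of the highest class level of either gene at E17.5, while Fabp2 stood at 23.4 CPM in fibroblast-like and 4228 CPM in epithelial-like cells. Free RNA from other cells cannot be told apart. Gm10260 in the deepest over the shallowest fibroblast-like cells stood at 0.971, near Col1a1 at 0.984 and Rps18 at 0.960. By the prediction written beforehand this value goes against free RNA. The free RNAs Hbb-bs, Fabp2, Apoa1 and Fabp1, however, stood at 6.66, 0.714, 0.685 and 0.564, none as low as predicted for free RNA. The prediction did not state this check, and with it the depth ratio decides nothing. The log2 ratios of Gm10260 lay within 0.40 of each other over the 4 classes, which is consistent with a difference of the whole library, such as reads shared with Rps18 or a strain variant, while those of Cwc22 lay 1.36 apart, so a library difference and one of stage cannot be told apart. No biological explanation was tested for either gene.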
